A study of Mus musculus with 24 samples.

How the data were processed

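RNA-seq of mouse pancreatic acinar cells was used, in 24 libraries of 8 groups: 2 genotypes (labelled WT, Ptf1a-CreERT; labelled KO, Pdx1 floxed with Ptf1a-CreERT), each at days 0, 1, 2 and 3 of culture with TGFα, with replicate numbers 0, 1 and 2. The series design text instead names a pancreatic cancer cell line, NB490; the sample labels, which describe primary acini, were followed. Per the labels' protocols, mice received tamoxifen by mouth daily for 5 days, acini were isolated with collagenase P and kept in Waymouth medium with soybean trypsin inhibitor and dexamethasone on non-adherent plates, ribosomal RNA was depleted, and libraries were sequenced as 50-cycle single-end reads.

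The deposited table gave FPKM per gene and library, on the linear scale, and those values were used as the authors made them. Per the submitters' processing notes, reads were checked with FastQC, aligned with TopHat2 2.0.9 on Bowtie2 2.1.0, and quantified with Cufflinks and Cuffdiff 2.1.1. The table had 27131 gene entries with 26493 symbols. For 636 symbols several entries were summed before testing, and the summed value stands for all of them. No counts and no per-library errors were used here, so the depth is unknown and the precision of a value rests only on the spread of the 3 libraries of a group. Summed FPKM differed several-fold between day 0 and later days, so the deposited scale is not a share of a fixed total.

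Genes with FPKM of at least 1 in at least 3 libraries were kept, which left 9797, and values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (1 linear model over the 8 groups, empirical Bayes with an intensity trend, Benjamini-Hochberg adjustment). A gene was called at an adjusted p under 0.05. The comparisons were each of days 1, 2 and 3 with day 0 within a genotype, labelled KO with labelled WT at each day, and an F-test of the 3 genotype by time terms. These 11 comparisons, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. All p-values of genes come from limma. Between genotypes, where most genes lay higher in labelled KO, changes of single genes are given from the same fit after median ratio scaling of the libraries, over genes with a mean FPKM of at least 1. The Pdx1 differences of its own paragraph and all genotype by time differences are from the deposited values, without this scaling.

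Gene lists were written from general knowledge of the pancreas and of the culture: digestive enzymes (29 members tested), acinar regulators and secretory genes (14), ductal and acinar-to-ductal metaplasia genes (19), EGFR and MAPK response (24), EMT (6), gastric and mucous genes (6), the Reg family (6), proliferation (19), unfolded protein response (20), inflammatory and NF-kB genes (14), glucocorticoid response (12), p53 response (13), cholesterol synthesis (19), hypoxia and glycolysis (16), markers of endocrine cells (10), leukocytes (8), fibroblasts and stellate cells (7) and endothelium (6), ribosomal proteins (81) and replication-dependent histones (39). A list of mitochondrial transcripts had 0 members in the table and was not tested. The other 20 lists were tested against all other genes with limma's camera at a preset correlation of 0.01 and adjusted over the 20 lists. The same test with a correlation estimated from the residuals was the alternative, and it is the stricter reading because genes of a list move together. Counts of list members were made with the adjustment over all genes and also with an adjustment over the list alone.

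Genes are named by a rule. Pdx1 comes first. Between genotypes the 8 called genes with the largest change in each direction are named, and in the other comparisons 3 per direction, among genes with non-overlapping libraries and a mean FPKM of at least 5 in the higher group. Symbols of unnamed models and small RNAs (Gm plus a digit, Rik endings and the like) are skipped. From each list the 3 members with the smallest p are eligible, as are called members that move against their list, and the text prints some of these. Genes named outside the rule are marked as chosen after their values were seen. Values of families with near-identical copies (Reg, Klk1 and Klk1b, Amy, Try, Cela, Hist and Rpl genes) are uncertain in which copy the reads came from, and 2 entries for Amy2a were listed at 0 in every library.

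The alternatives were a pseudocount of 0.1, no expression filter, median ratio scaling, quantile normalization, the replicate number as a block, a fit of only the groups compared, array weights, an absolute log2 change of at least 1, each table entry on its own, and leaving out each library in turn. A random block by replicate number within a genotype was added after the data were seen. For the pairing check, deviations of libraries from their group means were correlated between groups for equal replicate numbers: r was 0.19, 0.13 and 0.17 between day 0 and day 1 in labelled KO, all over 0.1. The equal numbers of these 3 pairs were therefore read as a pairing, on the data and not on the labels. Of 28 pairs of groups 7 had all 3 values over 0.1. The block itself was 1 factor for the replicate number over all libraries, so it also tied days and genotypes without such a correlation. Gene positions came from GENCODE M21 on GRCm38.

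The fit was tested on simulated data. Changed genes were drawn only from those well above the expression filter in labelled WT at day 0, so genes of lower FPKM were not tried. The simulated noise was independent between genes, and groups of unequal spread were not tried. For labelled KO against labelled WT at day 0, over 9528 simulated genes, the fit called 53.7% of genes changed by 0.5 on the log2 scale. It called 91.0% at 1 and 100% at 2, with 11 false calls, a count that holds for this noise only. With 1 uniform factor put on all labelled KO values it made 2357 false calls at day 0, and 24 after median ratio scaling. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.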

Results

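RNA was profiled, per the sample labels, from mouse pancreatic acini, the clusters of enzyme-secreting cells of the exocrine pancreas, at 4 times and in 2 genotypes, with 3 libraries in each of the 8 groups. All mice carried a tamoxifen-inducible Cre recombinase driven by Ptf1a, an acinar transcription factor gene, and were given tamoxifen. Mice with floxed alleles of Pdx1, a homeobox transcription factor of the pancreas, gave the libraries labelled KO, and mice without them gave the libraries labelled WT. Acini were collected at day 0 or after 1, 2 or 3 days in suspension with TGFα at 50 ng/mL, a ligand of the EGF receptor used to drive acinar cells toward a duct-like state (acinar-to-ductal metaplasia). No untreated culture of the same age was among the groups, so time in culture and TGFα could not be separated. The values were FPKM, and sequencing depth is unknown because the table holds no counts. FPKM are given as mean ± SD (n = 3 libraries) throughout, and for each gene named as called the 3 libraries of one group all lay beyond those of the other unless stated. The labels do not say whether the 3 libraries of a group came from separate animals, so part of the spread behind the p-values may be technical. Sex-linked genes put 1 library of female type and 2 of male type in each group, so a group came from at least 2 animals. Summed FPKM per library ranged from 1062000 to 1225400 in labelled WT and from 1003460 to 1306270 in labelled KO at day 0, and from 149526 to 166293 in all libraries of day 2. The digestive enzyme genes held 77.9% ± 0.582 of the summed FPKM in labelled WT at day 0 and 41.3% ± 1.3, 20.9% ± 1.23 and 16.5% ± 1.14 at days 1, 2 and 3. In labelled KO they held 73.8% ± 1.32, 33.1% ± 1.44, 14.3% ± 1.40 and 14.2% ± 1.08.

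Pdx1 itself, on chromosome 5 at 147269959 to 147275848 of GRCm38, went against the labels. It stood at 0.348 ± 0.0859 FPKM in labelled WT and 5.57 ± 1.25 in labelled KO at day 0, 16.0 times higher in the libraries named as knockout (log2 difference 2.27 ± 0.11 SE, adjusted p = 2.55e-10). The lowest labelled KO library of day 0 held 4.60 FPKM and the highest labelled WT library 0.436. At day 1 the means were 0.148 ± 0.0216 and 1.12 ± 0.281 FPKM (log2 difference 0.88, adjusted p = 0.000117). At day 2 they were 0.267 ± 0.0534 and 0.26 ± 0.0386 (log2 difference −0.01, adjusted p = 0.965), and at day 3 0.445 ± 0.0751 and 0.219 ± 0.132 (log2 difference −0.25, adjusted p = 0.118). Over the course Pdx1 fell in labelled KO, with log2 changes from day 0 of −1.62, −2.37 and −2.42 at days 1, 2 and 3 (adjusted p = 2.49e-10, 1.03e-12 and 8.51e-13). In labelled WT the changes were −0.23, −0.09 and 0.10, none past the threshold in this fit (adjusted p = 0.0731, 0.489 and 0.427). With a pseudocount of 0.1 the labelled WT day 1 change was −0.84 (adjusted p = 0.00515) and the day 3 difference between genotypes −0.84 (0.0339), so both passed. The day 1 change also passed after median ratio scaling (0.0389), quantile normalization (0.0293), with array weights (0.0161) and with a random block by replicate number within a genotype (0.0303), an alternative chosen after the data were seen. The labelled WT day 2 change passed under quantile normalization (−0.26, adjusted p = 0.0399), and the day 3 difference with array weights (0.000851). With the replicate number as a block, the labelled WT day 1 change (0.0214) and the day 3 difference between genotypes (0.0414) passed too. The sign of the day 2 difference turned with array weights (0.01). The FPKM covers the whole gene, so it cannot show whether the floxed part was present, and every direction between genotypes is therefore given between the libraries labelled KO and labelled WT.

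**Figure D1:**
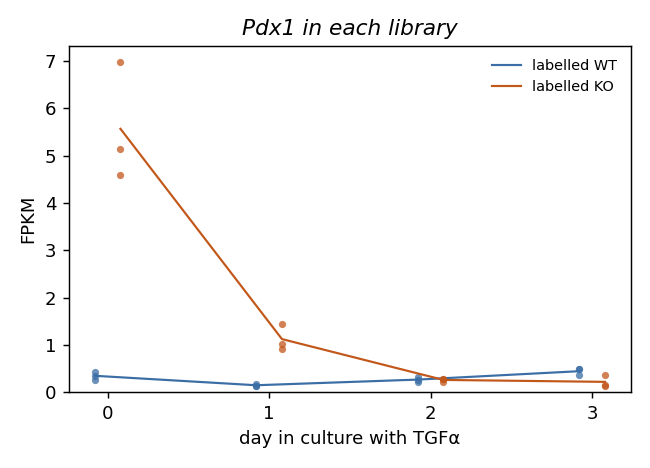
Pdx1 in each of the 24 libraries, as FPKM on a linear axis against day of culture, with labelled WT and labelled KO side by side. Points are libraries and lines join the means of n = 3. The labelled KO libraries held at least 4.60 FPKM at day 0, and both genotypes were under 0.5 at days 2 and 3.

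The course in labelled WT libraries asks how acini change under TGFα when Pdx1 carries no floxed allele. After 1 day, all 29 tested digestive enzyme genes were lower than at day 0, with a median log2 change of −3.39. Pla2g1b, the pancreatic phospholipase A2, fell from 1188 ± 159.6 to 98.2 ± 6.36 FPKM, the lipase-related gene Pnliprp2 from 2923 ± 179 to 278 ± 25.9, and carboxypeptidase A1 (Cpa1) from 37040 ± 3263 to 4168 ± 469.9. Of 14 acinar regulators and secretory genes 12 fell, among them the pancreatic disulfide isomerase gene Pdia2 (1730 ± 139 to 155 ± 28.4) and Bhlha15, a transcription factor of mature acini (14.3 ± 2.41 to 1.27 ± 0.0987). Xbp1, a factor of secretory cells, rose from 151 ± 9.06 to 272 ± 39.05. The largest falls by the naming rule were in Sgk1, a glucocorticoid-induced kinase (236 ± 13.2 to 3.96 ± 1.24), Serpini2, a pancreatic serine protease inhibitor (514 ± 87.3 to 9.84 ± 3.03), and Sesn1, a p53-responsive sestrin (101 ± 6.09 to 2.09 ± 0.151). The largest rises were in the phosphomannomutase gene Pmm1 (2.7 ± 0.821 to 63.7 ± 7.12), the β-defensin gene Defb1 (3.5 ± 0.816 to 73.95 ± 23.4) and neuropeptide Y (Npy, 4.11 ± 2.34 to 69.95 ± 39.9). All 12 glucocorticoid response genes fell although the medium contained dexamethasone, a glucocorticoid, whereas 15 of 19 cholesterol synthesis genes rose, for example Fdps, a step of the mevalonate pathway (6.38 ± 1.04 to 21.5 ± 1.88). The unfolded protein response list had 13 of 20 members lower and none higher, led by Herpud1 (314 ± 8.82 to 25.2 ± 1.82). Ductal genes split, with 7 of 19 higher, such as the tight junction gene Cldn4 (54.5 ± 12.6 to 409.5 ± 24.6) and clusterin (Clu, 668 ± 58.7 to 2752 ± 75.3), and 3 lower, including the mucin gene Muc1 (28.4 ± 5.38 to 6.41 ± 0.914). In the EGFR and MAPK list 7 of 24 rose, led by Ier3 (2.88 ± 0.662 to 49.7 ± 3.83), and 6 fell, led by the AP-1 gene Fosb (4.41 ± 0.439 to 0.101 ± 0.0275). Reg genes, secreted lectins whose close copies can share reads, also split: Reg1 fell from 36750 ± 7739 to 4383 ± 1013 and Reg3b rose from 1506 ± 527 to 2964 ± 579, with 3 of 6 higher and 2 lower. In all, limma called 6500 of 9797 genes, 3560 higher and 2940 lower. Among list tests the enzyme list (adjusted p = 1.18e-15; 0.0470 with an estimated correlation) and the glucocorticoid list (3.18e-07; 0.0470 with an estimated correlation) were lower in both versions. Called only with the preset correlation were the regulators (adjusted p = 6.08e-05; adjusted p = 0.0761 with an estimated correlation), unfolded protein response (adjusted p = 0.000295; adjusted p = 0.538 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.00163; adjusted p = 0.560 with an estimated correlation). Under quantile normalization Reg1 was not called (log2 change −0.14, adjusted p = 0.540). Counts adjusted over the list alone were the same as those over all genes for each of these lists. Also lower only with the preset correlation were ribosomal proteins (adjusted p = 3.28e-17; 0.526 with an estimated correlation), histones (adjusted p = 2.2e-06; 0.538 with an estimated correlation) and endocrine markers (adjusted p = 0.0200; 0.563 with an estimated correlation). The endocrine call was lost without labelled WT day 0 replicate 2 (adjusted p = 0.0643) or labelled WT day 1 replicate 0 (0.0521). The ductal (adjusted p = 0.46), EGFR and MAPK (0.791) and Reg (0.946) lists did not pass.

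By day 2 the enzyme list had fallen further, with all 29 genes lower and a median log2 change of −5.37 from day 0. Cel, the bile salt-activated lipase, went from 34620 ± 3208 to 317 ± 91.3 FPKM, Serpini2 to 1.08 ± 0.302 and the trefoil factor Tff2 from 3117 ± 188 to 28.2 ± 8.85. The top rises were the lipid droplet gene Plin2 (6.7 ± 1.91 to 144 ± 8.19), tissue plasminogen activator (Plat, 2.12 ± 0.413 to 60.5 ± 26.8) and Npy (84.04 ± 12.7 at day 2). Ductal genes had 11 of 19 members higher and 2 lower. The tetraspanin gene Tspan8 rose from 0.454 ± 0.148 to 5.34 ± 1.16 and Clu to 3778 ± 504, whereas the epithelial adhesion gene Epcam fell from 31.3 ± 4.47 to 23.1 ± 1.03, a call lost without labelled WT day 0 replicate 0 (adjusted p = 0.0854) and under quantile normalization (0.381). In the hypoxia and glycolysis list 10 of 16 rose, among them the glycolytic genes Eno1 (5.91 ± 1.11 to 50.1 ± 9.55) and Aldoa (70.6 ± 11.9 to 250.4 ± 31.2), and Ndrg1 was 1 of 3 that fell (146 ± 12.7 to 22.3 ± 3.11). Of 13 p53 response genes 8 rose, such as the apoptosis gene Bax (3.98 ± 0.717 to 27.5 ± 1.18), and 3 fell, with Sesn1 at 1.29 ± 0.2. Among inflammatory genes 5 of 14 rose (6 when adjusted over the list alone) and 5 fell; lipocalin 2 (Lcn2) rose from 13.8 ± 0.732 to 135 ± 29.2. EMT genes had 4 of 6 higher, such as Tgfb1 (0.252 ± 0.0882 to 2.18 ± 0.422). Markers of other cell types moved in different directions. Of 7 fibroblast and stellate markers 5 rose, such as the collagen gene Col1a1 (0.348 ± 0.0531 to 3.01 ± 0.981), and 2 fell, including decorin (Dcn, 8.6 ± 2.38 to 1.9 ± 0.748). Of 6 endothelial markers 5 fell, led by Plvap (3.64 ± 0.794 to 1.17 ± 0.472), and of 8 leukocyte markers 2 rose, among them Cd14 (3.21 ± 0.95 to 24.6 ± 5.95), and 3 fell. Of 10 endocrine markers 6 fell, led by transthyretin (Ttr, 31.8 ± 7.76 to 1.89 ± 0.378). Limma called 6838 genes, 4067 higher and 2771 lower. With either correlation the enzyme list (adjusted p = 2.39e-21 and 0.0201 with an estimated correlation), the regulators (10 of 14 lower; 3.2e-06 and 0.0328 with an estimated correlation) and the glucocorticoid list (12 of 12 lower; 2.12e-08 and 0.0262 with an estimated correlation) were lower. The endocrine list was lower only with the preset correlation (adjusted p = 0.0205; adjusted p = 0.706 with an estimated correlation) and lost that call without labelled WT day 0 replicate 2 (adjusted p = 0.0621). The preset correlation alone also called lower ribosomal proteins (adjusted p = 7.31e-12; 0.621 with an estimated correlation), the unfolded protein response (adjusted p = 3.18e-07; 0.330 with an estimated correlation) and histones (adjusted p = 1.49e-05; 0.621 with an estimated correlation). The ductal (adjusted p = 0.189), hypoxia (0.312), p53 (0.375), EMT (0.375), inflammatory (0.997), fibroblast (0.674), endothelial (0.160) and leukocyte (0.420) lists did not pass.

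At day 3 cell cycle genes joined the rises in labelled WT, with 17 of 19 proliferation genes higher than at day 0 (18 adjusted over the list alone), for example the replication helicase genes Mcm7 (1.67 ± 0.422 to 4.68 ± 0.255 FPKM) and Mcm3 (0.157 ± 0.0447 to 1.91 ± 0.674). The highest-ranked rises were Sprr1a, a cornified envelope protein of squamous epithelia (1.3 ± 0.205 to 85.1 ± 23.7), Plat (74.9 ± 18.9 at day 3) and the acyl-CoA thioesterase gene Acot1 (0.472 ± 0.115 to 31.2 ± 7.59). All 29 enzyme genes remained lower, and pancreatic lipase (Pnlip) went from 56690 ± 5164 to 70.1 ± 8.07, Cel to 44.5 ± 2.78 and the elastase gene Cela1 from 78420 ± 11320 to 161 ± 26.8. Gastric and mucous genes split sharply, with 4 of 6 higher, such as Tff1 (0.105 ± 0.00604 to 6.71 ± 1.92) and Anxa10 (0.277 ± 0.151 to 10.1 ± 3.46), and 2 lower, Tff2 (8.1 ± 3.33) and Agr2 (1.82 ± 1.23 to 0.0471 ± 0.00985). The list's median was 1.81, its mean −0.06 and the test not significant (direction up, adjusted p = 0.486). Of 19 ductal genes 13 rose, such as keratin 7 (Krt7, 2.15 ± 0.244 to 12.2 ± 2.94), and 3 fell, including keratin 8 (Krt8, 1352 ± 228 to 559.9 ± 27.7), for a list adjusted p of 0.127. The Krt8 change of −1.26 turned to 1.18 under quantile normalization. In the EGFR and MAPK list 9 of 24 rose, such as the phosphatase gene Dusp4 (0.27 ± 0.0647 to 4.33 ± 0.922), and 9 fell (adjusted p = 0.658). Of 39 tested replication-dependent histone genes, near-identical copies that can share reads, 11 rose and 14 fell (adjusted p = 0.193). Among 81 ribosomal protein genes 53 fell, such as Rpl10 (455 ± 51.1 to 172 ± 15.2), and 2 rose. The acinar regulators had 8 of 14 lower, and Ptf1a, which drives the Cre, rose from 3.3 ± 0.572 to 4.93 ± 0.769 (adjusted p = 0.0363). That call was lost after median ratio scaling (adjusted p = 0.0760) and without labelled WT day 0 replicate 1 or 2 (0.103 each) or labelled WT day 3 replicate 1 (0.101) or 2 (0.110). Limma called 6727 genes, 3912 higher and 2815 lower. The enzyme (adjusted p = 1.98e-22 and 0.0162 with an estimated correlation) and glucocorticoid lists (5.71e-08 and 0.0296 with an estimated correlation) were lower with either correlation. The proliferation call (adjusted p = 0.00362; adjusted p = 0.755 with an estimated correlation), the ribosomal call (adjusted p = 1.22e-06; adjusted p = 0.755 with an estimated correlation) and the regulator call (adjusted p = 0.000256; adjusted p = 0.119 with an estimated correlation) needed the preset correlation. Lists lower with the preset correlation alone included the unfolded protein response (adjusted p = 1.23e-07; 0.285 with an estimated correlation) and endocrine markers (adjusted p = 0.0325; 0.755 with an estimated correlation). The endocrine call was lost after median ratio scaling (adjusted p = 0.0610) and without labelled WT day 0 replicate 2 (0.0839) or labelled WT day 3 replicate 0 (0.0727).

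The same course was followed in labelled KO libraries, which asks how acini with floxed Pdx1 alleles respond. At day 1 all 29 enzyme genes were lower than at day 0 (median log2 change −3.57). Zg16, a zymogen granule protein, fell from 34800 ± 7273 to 1041 ± 156 FPKM, carboxypeptidase B1 (Cpb1) from 44710 ± 5870 to 1415 ± 309 and Sesn1 from 92.3 ± 7.88 to 2.04 ± 0.395. Plin2 (8.84 ± 2.42 to 137 ± 29.6), Plat (2.3 ± 0.0571 to 42.8 ± 16.5) and Ier3 (3.75 ± 0.426 to 55.96 ± 5.4) led the rises. Of the regulators 11 of 14 fell, among them Rbpjl, an acinar transcription factor (42.2 ± 1.18 to 3.11 ± 0.459), and Xbp1 rose from 160.1 ± 3.73 to 293 ± 25.96. No Reg gene rose, and 4 of 6 fell, such as Reg2 (27310 ± 12790 to 5542 ± 1365), for a list adjusted p of 0.0799. The Reg2 change of −2.21 turned to 1.22 under quantile normalization (adjusted p = 0.00199). Ductal genes had 9 of 19 higher and 3 lower (list adjusted p = 0.318), with Cldn4 going from 136 ± 11.7 to 536 ± 87.6. Of 19 cholesterol genes 16 rose and 2 fell, all 12 glucocorticoid genes fell, and 15 of 20 unfolded protein response genes fell. Limma called 6675 genes, 3628 higher and 3047 lower. With the preset correlation the enzyme list (adjusted p = 2.05e-16; adjusted p = 0.0622 with an estimated correlation) and the glucocorticoid list (adjusted p = 8.41e-07; adjusted p = 0.0628 with an estimated correlation) were lower. The regulators (adjusted p = 3.49e-05; adjusted p = 0.0681 with an estimated correlation) and unfolded protein response list (adjusted p = 3.17e-05; adjusted p = 0.448 with an estimated correlation) were also lower. Lower too were ribosomal proteins (adjusted p = 9.34e-17; 0.448 with an estimated correlation), histones (adjusted p = 8.41e-07; 0.448 with an estimated correlation) and endocrine markers (adjusted p = 0.0451; 0.613 with an estimated correlation). The endocrine call was lost after median ratio scaling (0.0706) and without labelled KO day 0 replicate 1 (0.0947) or labelled KO day 1 replicate 0 (0.0719) or 2 (0.0558). The cholesterol list was higher (adjusted p = 0.00527; adjusted p = 0.599 with an estimated correlation), so no list kept its call with an estimated correlation at day 1.

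At day 2 the top rises in labelled KO were Plat (144 ± 23.3 FPKM), Sprr1a (1.69 ± 0.533 to 97.2 ± 36.9) and Plin2 (197 ± 47.5). The top falls were the pancreatic ribonuclease Rnase1 (10330 ± 2129 to 38.8 ± 6.93), Zg16 (134 ± 18.6) and Cel (33920 ± 5333 to 153 ± 36.9). All 29 enzyme genes were lower, with a median log2 change of −5.95. Ductal genes had 10 of 19 higher, such as Tspan8 (0.498 ± 0.14 to 15.7 ± 1.7) and keratin 23 (Krt23, 7.38 ± 0.747 to 38.9 ± 12.4), and 2 lower. Of 16 hypoxia and glycolysis genes 10 rose and 3 fell, with Eno1 going from 4.98 ± 0.981 to 58.96 ± 2.24, and the list did not pass (adjusted p = 0.0592). Of 6 Reg genes 5 fell, and Reg1 went from 54820 ± 4817 to 953 ± 34.6. Limma called 6975 genes, 4011 higher and 2964 lower. The enzyme (adjusted p = 2.42e-21 and 0.0201 with an estimated correlation), regulator (10 of 14 lower; 1.28e-05 and 0.0482 with an estimated correlation) and glucocorticoid lists (12 of 12 lower; 9.76e-08 and 0.0386 with an estimated correlation) were lower with either correlation. The Reg list was lower only with the preset one (adjusted p = 0.00465; adjusted p = 0.356 with an estimated correlation). With the preset correlation alone, lower calls were also made for ribosomal proteins (adjusted p = 5.15e-10; 0.546 with an estimated correlation), the unfolded protein response (adjusted p = 3.97e-08; 0.249 with an estimated correlation), histones (adjusted p = 0.000153; 0.546 with an estimated correlation) and endocrine markers (adjusted p = 0.0236; 0.546 with an estimated correlation; 0.0548 without labelled KO day 0 replicate 1).

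At day 3 all 19 proliferation genes were higher than at day 0 in labelled KO, for example Mcm3 (0.282 ± 0.0846 to 3.6 ± 1.03 FPKM) and Mcm4 (0.339 ± 0.0404 to 2.96 ± 1.02). Sprr1a reached 162 ± 85.6, Plat 103 ± 33.5 and the calcium-binding gene S100a6 went from 3.91 ± 0.633 to 132 ± 43.3. Pnlip fell from 69040 ± 9006 to 68.4 ± 25.2, Cel to 46.1 ± 7.95 and the trypsin gene Try4, 1 of a family of close copies, from 40320 ± 4334 to 93.1 ± 39.6. Tff1 rose from 0.134 ± 0.073 to 13.01 ± 1.54 and Anxa10 from 0.557 ± 0.258 to 24.4 ± 1.13, while Tff2 fell from 2920 ± 239 to 7.85 ± 0.159. Of 19 ductal genes 11 rose, Tspan8 reaching 38.6 ± 8.71, and 3 fell. Gata4, a transcription factor of the regulator list, rose from 6.07 ± 0.507 to 8.21 ± 1.14 (adjusted p = 0.00918, and 0.0639 without labelled KO day 3 replicate 0), and 8 of its 14 members fell. Limma called 6793 genes, 3702 higher and 3091 lower. The enzyme list was lower with either correlation (adjusted p = 6.1e-21 and 0.0218 with an estimated correlation). The proliferation list was higher with the preset correlation (adjusted p = 1.18e-06; adjusted p = 0.566 with an estimated correlation), and the glucocorticoid list was lower (adjusted p = 1.18e-06; adjusted p = 0.0716 with an estimated correlation). Also lower only with the preset correlation were ribosomal proteins (adjusted p = 1e-08; 0.566 with an estimated correlation), the unfolded protein response (adjusted p = 1.46e-07; 0.290 with an estimated correlation), regulators (adjusted p = 0.000594; 0.166 with an estimated correlation) and endocrine markers (adjusted p = 0.0484; 0.566 with an estimated correlation). The Reg list (4 of 6 lower; adjusted p = 0.0444; adjusted p = 0.566 with an estimated correlation) lost its call after median ratio scaling (adjusted p = 0.0568) and without labelled KO day 0 replicate 0 (0.0513) or labelled KO day 3 replicate 2 (0.0558). The endocrine list lost its call after scaling (adjusted p = 0.0702) and without labelled KO day 0 replicate 0 (0.0513) or 1 (0.103) or labelled KO day 3 replicate 0 (0.0742) or 2 (0.0895).

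Set against each other gene by gene, the 2 courses ran together. At days 1, 2 and 3, 3102, 3572 and 3318 genes were higher than at day 0 in both genotypes, against 1318.3, 1665.1 and 1478.2 that independent lists of these sizes would share. Lower in both were 2606, 2483 and 2533 genes, against 914.38, 838.34 and 888.15. Opposite calls were made for 9, 12 and 12 genes. With an absolute log2 change of at least 1 required, the calls of each day numbered 1401, 1543 and 1500 in labelled WT and 1378, 1641 and 1629 in labelled KO. Without the expression filter the day 3 counts were 10171 and 10690. Pearson's r of the log2 changes was 0.887, 0.920 and 0.914 across genes, which are not independent replicates.

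**Figure D2:**
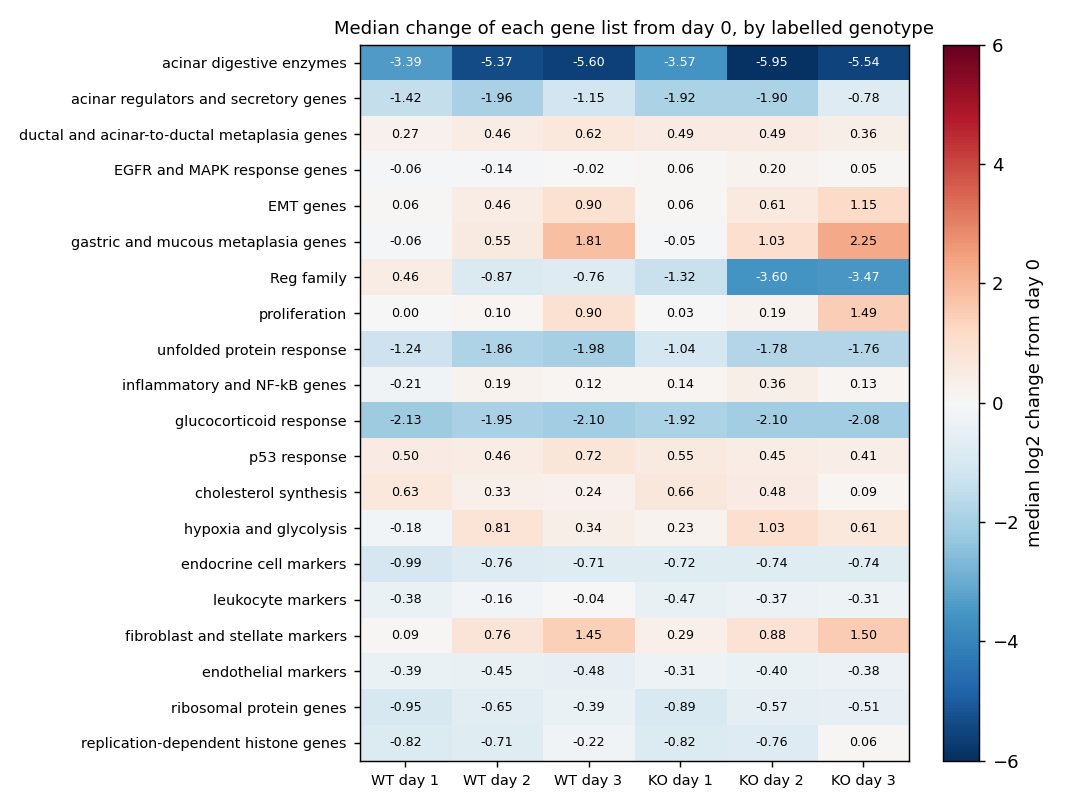
Median log2 change from day 0 of each gene list at days 1, 2 and 3, for labelled WT and labelled KO (n = 3 libraries per group). The digestive enzyme list lies lowest, at −5.60 in labelled WT and −5.54 in labelled KO at day 3.

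**Figure D3:**
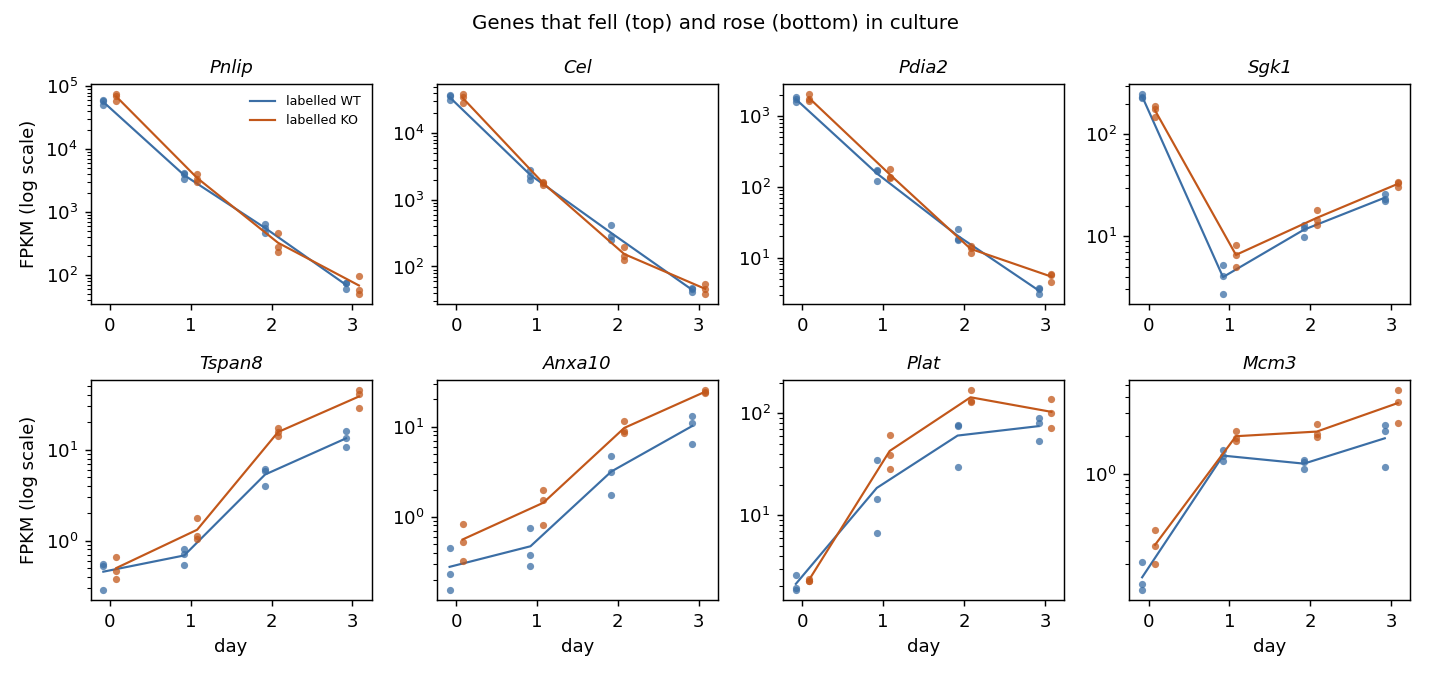
FPKM of selected genes on log axes against day of culture, each point 1 library and each line joining the means of n = 3, for labelled WT and labelled KO. The enzyme gene Pnlip fell from 56690 to 70.1 in labelled WT, while genes such as Plat rose.

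The genotype comparison at each time asks what differs between acini with and without floxed Pdx1 alleles. As deposited, almost all calls were higher in labelled KO: 2849 higher and 115 lower at day 0, 2648 and 62 at day 1, 2246 and 50 at day 2, and 1476 and 47 at day 3. The median log2 difference over all 9797 genes was 0.17, 0.17, 0.17 and 0.15. With each library divided by its median ratio to the geometric mean library, these medians became 0.04, 0.04, 0.04 and 0.05, and the calls became 445 higher and 179 lower, 217 and 74, 43 and 28, and 170 and 44. Quantile normalization gave 204 and 193, 113 and 104, 34 and 36, and 125 and 89. The genotype differences of single genes at each day below are therefore given relative to this shift, from the rescaled values, and a gene is said to have kept its call where it also passed there. Without rescaling, 32.8%, 50.8%, 53.7% and 42.3% of genes had non-overlapping libraries at days 0 to 3, where chance alone gives 10% for 3 against 3. Array weights raised the counts of all calls at days 1, 2 and 3 to 5145, 5248 and 5081 and lowered that of day 0 to 1795. Calls with an absolute log2 difference of at least 1 numbered 58, 58, 49 and 47.

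**Figure D4:**
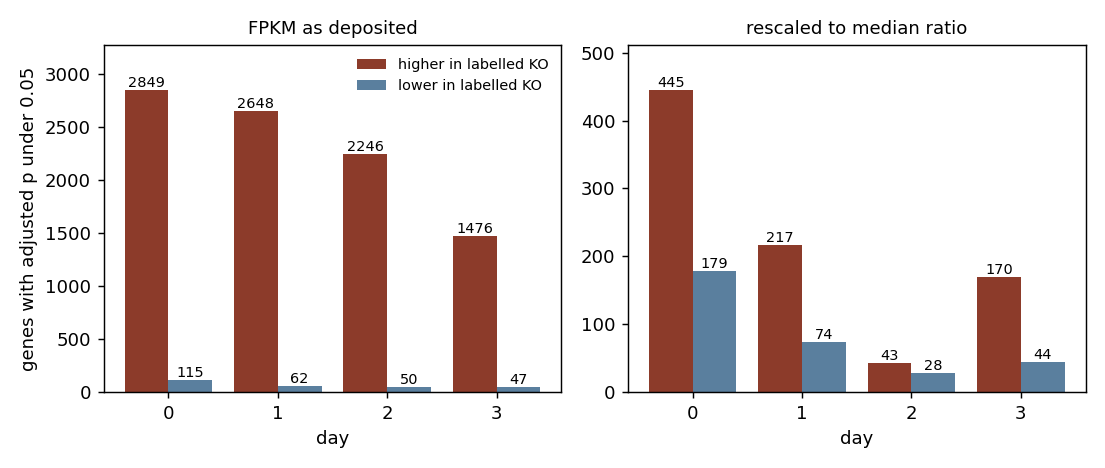
Number of genes higher and lower in labelled KO than in labelled WT at each day (limma, adjusted p under 0.05, n = 3 per group), as deposited and after median ratio scaling. At day 0 the calls were 2849 higher and 115 lower as deposited, and 445 and 179 after scaling.

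At day 0, before culture, Reg genes were higher in labelled KO. Reg3a stood at 228 ± 159.5 FPKM in labelled WT and 1254 ± 206 in labelled KO (log2 difference 2.70, adjusted p = 0.00414), Reg2 at 7333 ± 5186 and 27310 ± 12790 (1.87, 0.02) and Reg3b at 1506 ± 527 and 5461 ± 549 (1.72, 8.9e-05). Of 6 Reg genes 5 were higher as deposited (all 6 adjusted over the list alone) and 4 after scaling. Called higher in the unfolded protein response list, whose test did not pass, were the stress transcription factor Ddit3 (4.59 ± 1.55 against 21.3 ± 4.57, 1.85, adjusted p = 0.00226), the chaperone gene Hsp90b1 (41.2 ± 8.87 against 100 ± 30.3) and the disulfide isomerase gene Pdia4 (8.92 ± 2.23 against 31.4 ± 15.5). In that list 8 of 20 were higher and 1 lower (9 and 1 adjusted over the list alone), and 6 and 1 after scaling. Brain-type creatine kinase (Ckb) was higher too (2.67 ± 3.57 against 15.4 ± 6.4, 2.40, adjusted p = 0.0166). Ductal genes had 6 of 19 higher as deposited (9 adjusted over the list alone), where 2849 of all 9797 genes were, and 3 of 20 after scaling, among them Cldn4 (54.5 ± 12.6 against 136 ± 11.7) and keratin 20 (Krt20, 6.91 ± 0.42 against 22 ± 5.23). Lower in labelled KO were Serpini2 (514 ± 87.3 against 34.4 ± 20.9, log2 difference −4.25, adjusted p = 2.31e-07) and the secretory pathway gene Tmed11 (56.04 ± 17.2 against 16.1 ± 4.95, −1.94). Lower too were the neuropeptide galanin (Gal, 34.3 ± 13.4 against 9.75 ± 4.35, −1.90) and Frmd6 (6.03 ± 0.326 against 2.89 ± 0.481, −1.03). Of the enzymes, Cela1 (78420 ± 11320 against 37170 ± 7776, −1.29) and the chymotrypsin-like gene Ctrl (29070 ± 2597 against 16440 ± 4508, −1.06) were lower, and Pla2g1b was higher only as deposited (1188 ± 159.6 against 1900 ± 352, adjusted p = 0.095 after scaling). The insulin gene Ins2 stood at 226 ± 135 and 65.5 ± 39.1 (−1.99, adjusted p = 0.033), and 4 of 10 endocrine markers were lower (5 after scaling) while Ttr was higher (31.8 ± 7.76 against 61.95 ± 19.6). Rufy4 was lower (10.3 ± 11.1 against 0.683 ± 0.041, −2.46), and the complement gene C4b and the liver-type inhibitor gene Itih4 were higher only as deposited (adjusted p = 0.12 and 0.165 after scaling). List tests were higher for Reg genes (adjusted p = 0.00425; adjusted p = 0.288 with an estimated correlation). They were lower for endocrine markers (adjusted p = 1.8e-08; adjusted p = 0.128 with an estimated correlation) and glucocorticoid genes (3 of 12 lower, 4 after scaling; adjusted p = 3.62e-06; adjusted p = 0.128 with an estimated correlation). The enzyme list was also lower (adjusted p = 0.000202; adjusted p = 0.322 with an estimated correlation), although its deposited median of 0.10 and mean of 0.11 had the opposite sign. Only the preset correlation gave the further lower calls of hypoxia and glycolysis (adjusted p = 3.62e-06; 0.128 with an estimated correlation), EGFR and MAPK genes (adjusted p = 0.000245; 0.246 with an estimated correlation), regulators (adjusted p = 0.00248; 0.203 with an estimated correlation), histones (adjusted p = 0.00434; 0.577 with an estimated correlation), endothelial markers (adjusted p = 0.00675; 0.424 with an estimated correlation) and proliferation (adjusted p = 0.0285; 0.670 with an estimated correlation). These tests are relative to all other genes. The deposited medians of EGFR and MAPK genes (0.03), regulators (0.05), histones (0.13) and proliferation (0.11) were above 0. After median ratio scaling histones (adjusted p = 0.617), endothelial markers (0.0736) and proliferation (0.930) did not pass. They also did not pass without labelled KO replicate 1 (0.220, 0.0520 and 0.155) or labelled WT replicate 0 (0.606, 0.131 and 0.0872). Proliferation did not pass without labelled WT replicate 1 (0.0888) either. The unfolded protein response (adjusted p = 0.438) and ductal (0.289) lists did not pass. In a fit of the day 0 libraries alone 45 genes were called. Of the genes named, Ddit3, Reg3b, Cldn4, Krt20, Serpini2, Tmed11 and Frmd6 were among them, and the others had adjusted p from 0.0569 (Cela1) to 0.190 (Itih4). As deposited, Rufy4 lost its call without labelled WT replicate 2 (adjusted p = 0.0688), Ins2 without labelled WT replicate 2 (0.0965) or labelled KO replicate 2 (0.0986), and Ctrl without labelled WT replicate 0 (0.0699), labelled WT replicate 1 (0.0525) or labelled KO replicate 2 (0.127). C4b and Itih4 lost theirs without labelled WT replicate 1 (0.186 and 0.291).

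At day 1 some acinar genes were lower in labelled KO, and the enzyme and regulator lists were lower relative to all other genes. Cela1 stood at 7282 ± 1089 FPKM in labelled WT and 2440 ± 518 in labelled KO (log2 difference −1.77, adjusted p = 0.000275) and Rnase1 at 816 ± 171 and 417 ± 66.8 (−1.14). Ctrl stood at 1753 ± 266 and 774 ± 169 (−1.38) and Cpa1 at 4168 ± 469.9 and 2619 ± 136 (−0.85). Of 29 enzymes 4 were lower and 1, Pla2g1b, was higher as deposited; after scaling 4 were lower and none higher. Of 14 regulators 4 were lower on either scale, among them Rbpjl (5.36 ± 0.305 against 3.11 ± 0.459, −0.78) and the gap junction gene Gjb1 (7.92 ± 1.14 against 4.6 ± 0.489, −0.82), and Gata6 was higher as deposited only (adjusted p = 0.364 after scaling). Serpini2 (9.84 ± 3.03 against 0.549 ± 0.333, −2.90), angiogenin (Ang, 16.2 ± 4.04 against 6.25 ± 0.861, −1.40), the noncoding host gene Snhg6 (30.3 ± 9.92 against 10.8 ± 1.21, −1.54) and the kallikrein gene Klk1b11, 1 of a family of close copies (29.1 ± 6.77 against 13.1 ± 4.86, −1.31), were also lower. Higher in labelled KO were Apobec3, an antiviral cytidine deaminase (1.12 ± 1.11 against 6.88 ± 1.14, log2 difference 1.88, adjusted p = 0.00335), Phldb2 (2.57 ± 1.4 against 9.64 ± 2.68, 1.46) and Fam107b (2.07 ± 0.104 against 8.29 ± 2.48, 1.42). Higher too were the tetraspanin gene Tspan1 (10 ± 1.82 against 30.2 ± 10.1, adjusted p = 0.000526), annexin A3 (Anxa3, 23.5 ± 3.94 against 65.2 ± 6.58, 1.26) and filamin A (Flna, 13.4 ± 1.92 against 33.8 ± 3.58, 1.10). Ductal genes had 10 of 19 higher as deposited (11 adjusted over the list alone) and 1 after scaling, Krt23 (11.3 ± 2.4 against 27.5 ± 6.49, 1.04; list adjusted p = 0.0872). Ckb, Sprr1a, Ins2 and the islet amyloid gene Iapp were called as deposited only (adjusted p = 0.14, 0.114, 0.0999 and 0.0782 after scaling); Iapp stood at 24.3 ± 12.8 and 6.34 ± 2.62. The enzyme list (adjusted p = 4.67e-16 and 0.0315 with an estimated correlation) and the regulators (3.27e-08 and 0.0274 with an estimated correlation) were lower with either correlation, and endocrine markers (adjusted p = 1.19e-09; adjusted p = 0.0725 with an estimated correlation; 2 of 10 lower, none after scaling) with the preset one. No member was called in the other lists that were lower only with the preset correlation, histones (adjusted p = 3.21e-05; 0.437 with an estimated correlation), proliferation (adjusted p = 0.00589; 0.702 with an estimated correlation), endothelial markers (adjusted p = 0.0183; 0.437 with an estimated correlation), Reg genes (adjusted p = 0.0393; 0.437 with an estimated correlation) and p53 response genes (adjusted p = 0.0437; 0.437 with an estimated correlation). None of these 5 passed after median ratio scaling (adjusted p = 0.242, 0.575, 0.242, 0.242 and 0.0833). All but endothelial markers had a deposited median above 0 (0.06, 0.05, 0.07 and 0.08). The endothelial, Reg and p53 calls were each lost without labelled WT replicate 0 (0.0877, 0.0517 and 0.0517) and without 1 or 2 other libraries. Cpa1 was not called without the expression filter (adjusted p = 0.0649), nor Ctrl under quantile normalization (0.0716). The count of 2710 genes fell to 1351 without labelled KO replicate 1, to 1583 without labelled WT replicate 2 and to 1804 without labelled KO replicate 0. Klk1b11 lost its call without labelled WT replicate 1 (adjusted p = 0.0517), labelled WT replicate 2 (0.0750) or labelled KO replicate 1 (0.105).

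At day 2 the enzyme list was lower in labelled KO in 10 of 29 members (11 adjusted over the list alone; 9 after scaling) and higher in none. Cela1 stood at 857 ± 165 FPKM in labelled WT and 206 ± 67.1 in labelled KO (log2 difference −2.26, adjusted p = 4.76e-05) and Rnase1 at 99.7 ± 13.5 and 38.8 ± 6.93 (−1.52). Ctrl stood at 421 ± 74.7 and 169 ± 48.6 (−1.51) and Cel at 317 ± 91.3 and 153 ± 36.9 (−1.21). Snhg6 was lower as well (32.7 ± 9.72 against 11.1 ± 0.738, −1.60), as were the metallothionein genes Mt1 (1079 ± 150.2 against 702 ± 123, −0.80) and Mt2 (384 ± 64.2 against 230.0 ± 35.1, −0.91). Higher in labelled KO were Apobec3 (1.54 ± 1.08 against 7.18 ± 0.466, log2 difference 1.62, adjusted p = 0.0182) and the epidermal gene Crct1 (2.22 ± 1.08 against 8.8 ± 1.84, 1.49). Fam107b (9.33 ± 3.17 against 27.5 ± 3.35, 1.34) and Tspan8 (5.34 ± 1.16 against 15.7 ± 1.7, 1.25) were higher as well. Gastric and mucous genes had 3 of 6 higher, of which Anxa10 (3.17 ± 1.48 against 9.66 ± 1.71, 1.25) and Tff1 (0.552 ± 0.144 against 1.65 ± 0.232, 0.68) kept the call after scaling. In the EGFR and MAPK list 7 of 24 were higher, of which the EGF receptor ligand gene Hbegf kept the call (2.18 ± 0.555 against 4.78 ± 0.251, 0.74). Called as deposited only were osteopontin (Spp1, 47.1 ± 30.8 against 153 ± 23.9, adjusted p = 0.272 after scaling), the cyclooxygenase gene Ptgs2 (0.0819 after scaling), Cpa4 (0.0667), Sprr1a (0.14), Rufy4 (0.14), Iapp (0.0819), Ins2 (0.0853) and Ins1 (0.172). Lists lower with either correlation were enzymes (adjusted p = 1.16e-37 and 0.00127 with an estimated correlation), regulators (3 of 14 lower and 1 higher, 1 and none after scaling; 1.49e-05 and 0.0384 with an estimated correlation), endocrine markers (3 of 10 lower, none after scaling; 6.65e-14 and 0.0305 with an estimated correlation) and p53 response genes (1.83e-05 and 0.0384 with an estimated correlation). None of the 13 p53 genes was called alone, and that list's median was 0.04 as deposited and −0.13 after scaling. Further lower lists, with the preset correlation alone, were glucocorticoid genes (adjusted p = 0.000288; 0.119 with an estimated correlation), Reg genes (adjusted p = 0.000608; 0.157 with an estimated correlation), endothelial markers (adjusted p = 0.00128; 0.358 with an estimated correlation), leukocyte markers (adjusted p = 0.0232; 0.461 with an estimated correlation) and histones (adjusted p = 0.0261; 0.695 with an estimated correlation). The histone median was 0.21 as deposited. Its test turned in direction after scaling (adjusted p = 0.705) and did not pass without labelled WT replicate 1 (0.0997) or labelled KO replicate 0 (0.0925). Leukocyte markers did not pass after scaling (0.372) or without labelled WT replicate 0 (0.325) or labelled KO replicate 0 (0.0925). Endothelial markers did not pass without labelled WT replicate 0 (0.0845). Higher with the preset correlation alone were ribosomal proteins (21 of 81 higher, none after scaling; adjusted p = 0.0130; 0.741 with an estimated correlation). That call was lost after scaling (0.0594) and without labelled WT replicate 0 (0.182) or labelled KO replicate 1 (0.174) or 2 (0.325). The ductal list had 9 of 19 higher as deposited and 1 of 20 after scaling, and did not pass (adjusted p = 0.0542). The EGFR and MAPK list (adjusted p = 0.239) and the gastric list (0.905) did not pass. The count of 2296 genes fell to 533 without labelled WT replicate 2, to 640 without labelled KO replicate 1, to 911 without labelled KO replicate 0 and to 1267 without labelled WT replicate 1. Mt1 and Mt2 lost their calls without labelled WT replicate 2 (adjusted p = 0.0693 and 0.0509).

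At day 3 proliferation genes were higher in labelled KO, 16 of 19 as deposited (18 adjusted over the list alone) and 10 after scaling. Cyclin B1 (Ccnb1) stood at 1.1 ± 0.654 FPKM in labelled WT and 3.4 ± 1.29 in labelled KO (log2 difference 0.98, adjusted p = 0.0138) and cyclin B2 (Ccnb2) at 0.742 ± 0.494 and 2.22 ± 0.646 (0.83). Higher too were prostatic acid phosphatase (Acpp, 0.43 ± 0.097 against 5.37 ± 2.79, 1.99, adjusted p = 0.000156), mesothelin (Msln, 10.8 ± 5.85 against 35.8 ± 9.47, 1.64) and Basp1 (0.756 ± 0.196 against 5.05 ± 2.41, 1.62). So were Apobec3 (1.9 ± 1.14 against 7.33 ± 1.08, 1.47), Tspan8 (13.4 ± 2.66 against 38.6 ± 8.71, 1.32), the aldo-keto reductase gene Akr1c19 (1.68 ± 0.936 against 5.87 ± 1.88, 1.27) and Prap1 (2.13 ± 1.05 against 6.43 ± 1.03, 1.19). Gastric and mucous genes had 3 of 6 higher (4 adjusted over the list alone), namely Tff1 (6.71 ± 1.92 against 13.01 ± 1.54, 0.75), Anxa10 (10.1 ± 3.46 against 24.4 ± 1.13, 1.10) and Cldn18, a stomach tight junction gene (1.33 ± 0.416 against 2.61 ± 0.595, 0.54). Of 20 unfolded protein response genes 9 were higher (10 adjusted over the list alone) and 5 after scaling, such as Manf (5.61 ± 1.3 against 11.6 ± 2.71, 0.80) and Hsp90b1 (18.9 ± 2.65 against 40.7 ± 9.74, 0.91). Lower in labelled KO were Lcn2 (178 ± 11.1 against 74.3 ± 12.2, −1.41, adjusted p = 0.000245), the kallikrein Klk1 of the enzyme list (225 ± 55.8 against 90.98 ± 16.01, −1.43) and Snhg6 (35.1 ± 8.16 against 12.03 ± 0.67, −1.58). Lower too were the surface antigen Ly6a (95.2 ± 24.6 against 42.1 ± 9.74, −1.29) and Cela1 (161 ± 26.8 against 80.9 ± 10.8, −1.13). Called as deposited only were Spp1 (adjusted p = 0.168 after scaling), Klk1b3 (0.06), Iapp (0.0552) and Ins2 (0.0513). The proliferation list was higher (adjusted p = 2.39e-10; adjusted p = 0.318 with an estimated correlation). So were histones (14 of 39 higher and none after scaling; adjusted p = 0.00700; adjusted p = 0.526 with an estimated correlation). The unfolded protein response (adjusted p = 0.00990; adjusted p = 0.498 with an estimated correlation) and gastric genes (adjusted p = 0.0296; adjusted p = 0.166 with an estimated correlation) were higher as well. The enzyme list was lower (4 lower and 1 higher, 4 and none after scaling; adjusted p = 8.36e-08; adjusted p = 0.166 with an estimated correlation), with a deposited median of 0.02 that is opposite in sign. Lower too, only with the preset correlation, were endocrine markers (2 of 10 lower, none after scaling; adjusted p = 4.22e-11; 0.126 with an estimated correlation), ribosomal proteins (adjusted p = 0.000314; 0.568 with an estimated correlation), p53 response genes (adjusted p = 0.00152; 0.166 with an estimated correlation), leukocyte markers (adjusted p = 0.0262; 0.498 with an estimated correlation), regulators (adjusted p = 0.0274; 0.393 with an estimated correlation) and endothelial markers (adjusted p = 0.0495; 0.498 with an estimated correlation). The regulators had 3 of 14 higher and 1 lower as deposited, and none higher and 1 lower after scaling. Their deposited median (0.06) and that of ribosomal proteins (0.08) were above 0. After scaling leukocyte markers (adjusted p = 0.283), regulators (0.0810) and endothelial markers (0.283) did not pass. Each also lost the call without any 1 of 3, 3 and 4 of the 6 libraries compared, in that order. In a fit of the day 3 libraries alone 4 genes were called, and the genes named had adjusted p from 0.0525 (Lcn2) to 0.0732 (Ccnb1). The count of 1523 fell to 297 without labelled WT replicate 2, to 539 without labelled KO replicate 0, to 646 without labelled KO replicate 1 and to 962 without labelled WT replicate 1. The histone call was lost without labelled WT replicate 2 (adjusted p = 0.167), and the gastric call without labelled KO replicate 1 (0.0755). That of Cldn18 was lost without labelled WT replicate 2 (0.0576), and the unfolded protein response call without labelled WT replicate 1 (0.0624) or labelled KO replicate 1 (0.0652). Ly6a lost its call without labelled WT replicate 0 (0.0723), labelled KO replicate 0 (0.0639) or labelled KO replicate 2 (0.0588).

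Called at all 4 days after scaling, 3 genes were higher in labelled KO (Apobec3, Als2cr4 and Zdhhc9) and 3 were lower (Cela1, Shisa4 and Gm26624), where independent lists of these sizes would share 0.000752 and 1.74e-05 by chance. These chance values hold only if the days are independent, and libraries of different days may come from the same animals. Of these, Als2cr4, Zdhhc9, Shisa4 and Gm26624 were chosen for naming after their values were seen. Shisa4, whose libraries overlapped at day 0, lost the call there (adjusted p = 0.0496 as deposited) without any of 5 of the 6 libraries compared, as did Gm26624 at day 3 (0.0291). Without the expression filter Shisa4 was not called at days 0 and 1 (adjusted p = 0.0838 and 0.0591), nor Gm26624 at day 3 (0.0506). Under quantile normalization Als2cr4 (adjusted p = 0.115 and 0.0513) and Zdhhc9 (0.0712 and 0.0777) were not called at days 0 and 1. In fits of only the groups compared the call was lost by Cela1 (0.0569), Zdhhc9 (0.0870) and Shisa4 (0.161) at day 0, by Shisa4 at day 1 (0.0672), and by all 6 at day 3 (from 0.0525 for Zdhhc9 to 0.0822 for Gm26624). As deposited 316 genes were higher and 6 lower at all 4 days. Apobec3 lies on chromosome 15 at 79891659 to 79915906 of GRCm38, and Cela1 on the same chromosome at 100674421 to 100687921.

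**Figure D5:**
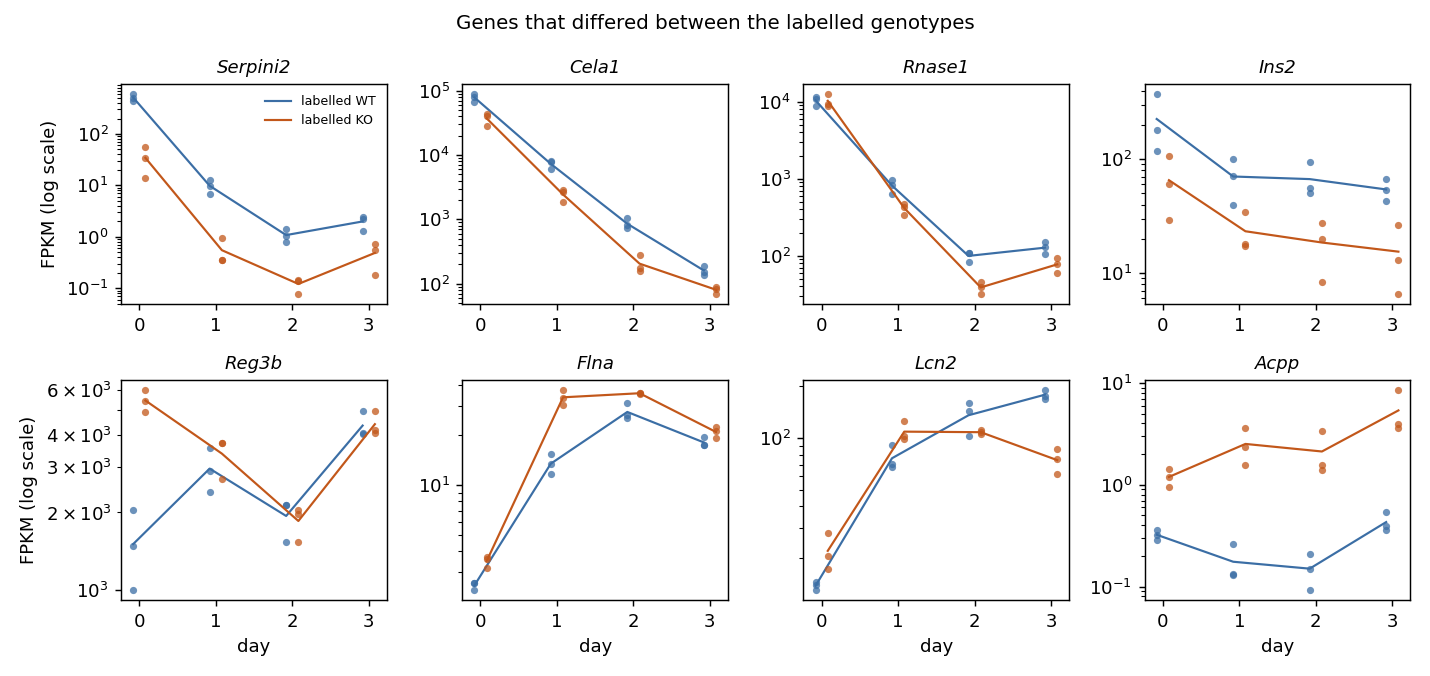
FPKM per library on log axes for genes that differed between genotypes, labelled WT and labelled KO side by side at each day, with means of n = 3. Cela1 was lower in labelled KO at each day, with means of 78420 and 37170 at day 0 and 161 and 80.9 at day 3.

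The genotype by time test asks whether the course itself differed; its differences are from the deposited values. For Serpini2, on chromosome 3 at 75242370 to 75270078 of GRCm38, the log2 difference at day 2 lay 3.17 above that at day 0 (adjusted p = 0.00216), with means of 1.08 ± 0.302 and 0.121 ± 0.0386 FPKM at day 2. In ratio the gap stayed, with labelled KO at 0.0670 of labelled WT at day 0 and 0.112 at day 2. The lower level of Tmed11 was gone by day 3, with means of 4.27 ± 1.99 and 6.45 ± 3.3 (2.21, adjusted p = 0.0409). Lcn2 stood at 13.8 ± 0.732 and 22.1 ± 5.59 at day 0, a difference that was not called after scaling. At day 3 its means were 178 ± 11.1 and 74.3 ± 12.2 (−1.88, adjusted p = 0.000894). The Reg3b difference of day 0 was gone by day 2, with means of 1938 ± 345 and 1853 ± 276 (−1.97, adjusted p = 0.00510). Basp1 moved apart, from 0.201 ± 0.0706 and 0.438 ± 0.182 to 0.756 ± 0.196 and 5.05 ± 2.41 (1.46, adjusted p = 0.0443), and Pdx1 had the smallest p of the genes named (−2.52 at day 3, adjusted p = 5.74e-08). In all 114 of 9797 genes had a course that differed (limma, F-test of the 3 interaction terms), 99 after scaling. The count fell to 61 without labelled WT day 0 replicate 2 and to 75 without labelled WT day 1 replicate 1 or labelled KO day 3 replicate 0, and rose to 211 without labelled WT day 0 replicate 0. With a pseudocount of 0.1 it was 71, and Serpini2 (adjusted p = 0.147), Tmed11 (0.15) and Basp1 (0.231) were no longer called; Tmed11 and Basp1 also lost the call without the filter (0.0637 and 0.0688) and in most fits that left out 1 library, Basp1 after median ratio scaling (0.0564), and Tmed11 under quantile normalization (0.0750). Reg3b lost its call under quantile normalization (adjusted p = 0.618). The count was 847 with array weights, 334 with a random block by replicate number within a genotype (an alternative chosen after the data were seen), 201 without the expression filter and 28 with an absolute log2 difference of at least 1.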

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

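The tests of islet cells, of the shift of all genes and of exchanged labels for Pdx1, of the enzyme share, and of fewer islet cells were chosen after the result was seen; all others in this part were planned.

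Of 113 genes named in the report, 16 had a course that differed between genotypes by the F-test of the genotype by time terms (limma, adjusted p under 0.05, n = 3 per group), which is what marked each of them; the value is the largest change from day 0 in the log2 difference of labelled KO from labelled WT. Pdx1 lost its day 0 difference by day 3 (−2.52, adjusted p = 5.74e-08). Frmd6 lost its day 0 difference by day 1 (0.963, adjusted p = 0.000894). Lcn2 became lower in labelled KO by day 3 (−1.88, adjusted p = 0.000894). Flna became higher in labelled KO at day 1 (0.911, adjusted p = 0.00106). Serpini2 had a smaller log2 difference at day 2 (3.17, adjusted p = 0.00216), when its means were 1.08 FPKM in labelled WT and 0.121 in labelled KO, but its ratio stayed low (0.0670 at day 0, 0.112 at day 2) and the call was lost with a pseudocount of 0.1 (adjusted p = 0.147). Ang became lower in labelled KO at day 1 (−1.78, adjusted p = 0.00338). Reg3b lost its day 0 difference by day 2 (−1.97, adjusted p = 0.00510). Tspan8 became higher in labelled KO by day 3 (1.41, adjusted p = 0.00834), as did Akr1c19 (1.38, adjusted p = 0.0164), Tff1 (0.850, adjusted p = 0.0183), Prap1 (1.25, adjusted p = 0.0245) and Basp1 (1.46, adjusted p = 0.0443). Tspan1 had its largest change at day 3 (−0.862, adjusted p = 0.0164). Cldn4 lost its day 0 difference by day 3 (−1.28, adjusted p = 0.0356). Tmed11 closed its gap by day 3 (2.21, adjusted p = 0.0409). Gjb1 had its largest change at day 3 (0.650, adjusted p = 0.0460). After median ratio scaling Tff1 (adjusted p = 0.0532), Basp1 (0.0564) and, by a small margin, Prap1 did not pass. The other alternatives were followed for 6 of the 16, Pdx1, Serpini2, Tmed11, Lcn2, Reg3b and Basp1. Tmed11 and Basp1 lost the call with a pseudocount of 0.1 (0.15 and 0.231), without the filter (0.0637 and 0.0688) and in most fits that left out 1 library. Under quantile normalization Tmed11 (0.0750) and Reg3b (0.618) lost it.

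Pdx1 was 16.0 times higher in the libraries labelled KO at day 0, the opposite of a lost transcript. Islet cells carried over into those preparations would raise insulin genes as well, yet the median rescaled log2 difference of Ins1, Ins2 and Iapp was −1.94. The shift of all genes was too small, since Pdx1 kept a difference of 2.20 after scaling. Exchanged genotype labels cannot be told apart from the labels as given: they would put the higher Pdx1 in true WT at day 0, but the day 3 difference was −0.249 (adjusted p = 0.118), or −0.84 with a pseudocount of 0.1 (adjusted p = 0.0339), and the day 2 difference was −0.01. A transcript that is stable or overproduced after loss of the floxed part was not tested, because the FPKM spans the whole gene.

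Most genes lay higher in the libraries labelled KO at each day. A scaling factor common to all genes of a library predicted equal medians at all expression levels, and in genes with a mean FPKM of at least 10 the medians of 5 expression levels, of 339 or 340 genes each, differed by at most 0.0778 within a day, with the largest range at day 3 (from 0.163 to 0.0852 at the highest level). If summed FPKM were equal in all libraries of a day, the smaller enzyme share of labelled KO would give shifts of 0.246, 0.189, 0.117 and 0.0383 at days 0 to 3. The observed medians of log2(FPKM + 1) were 0.17, 0.171, 0.168 and 0.147. On that premise the share falls short at day 3, and at day 2 by more than 2 of its SE (0.0186). Days 0 and 1 are left open. The premise did not hold at day 3, where summed FPKM was 150662 to 160803 in labelled WT and 163954 to 170544 in labelled KO. The added 1 also shrinks the medians, so the test cannot decide how much of the shift the share carries. A real rise of nearly all transcripts would look the same as a scaling factor, and no spike-in control was used here to separate them.

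The mean rescaled log2 difference of Ins1, Ins2 and Iapp was −1.94, −1.71, −1.97 and −1.94 at days 0 to 3 (SE 0.572); as deposited Ins2 and Iapp were called lower at all 4 days and Ins1 at days 0 and 2, and after scaling the 3 genes only at day 0. Fewer islet cells alone would lower the glucagon gene Gcg equally, but the insulin and Iapp genes lay below it by at least 1.24 (log2 difference −1.24, SE 0.271). Gcg itself differed by −0.696, −0.464, −0.698 and −0.667 (SE 0.391, not called), so fewer islet cells could account for part of the difference. Without labelled WT replicate 2, which was high in these genes, the difference of the mean was still −1.38 (SE 0.573) on the day where it was smallest. A loss restricted to β-cells, or lower insulin expression within them, was not tested.

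Regrouping the libraries gave few sets to compare with. For each of the 10 comparisons of 2 groups there are 10 ways to split 3 against 3, too few for a share under 0.05, and in each only the real split, 1 of 10, reached the real count of calls. The highest count of another split was 1, 0 and 1 for labelled WT at days 1, 2 and 3 (real 6500, 6838 and 6727), 1, 0 and 1 for labelled KO (real 6675, 6975 and 6793), and 764, 69, 0 and 27 between genotypes at days 0 to 3 (real 2964, 2710, 2296 and 1523). For the genotype by time test 4 of 100 assignments of genotype within days reached the real 114 genes, and the highest other gave 614, which points to a structure of the samples. A share of 0.04 leaves chance alone an unlikely source of the 114 only if libraries of different days are independent. The assignments ignore replicate numbers, and if these mark animals, exchanging whole animals leaves 10 splits, too few for a share under 0.05. Exchanging genotype on some days turns a steady genotype difference into a genotype by time term, so that structure can be genotype itself, or the animals.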

How the results depend on the processing

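The random block within a genotype was chosen after the data were seen; the other alternatives were planned.

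The counts of the 6 course comparisons stayed within 1.5 times under 8 of the 10 alternatives named beforehand. Of 214 gene results 118 kept direction and side of the threshold throughout, and of 85 list calls 17 did so. With an estimated correlation 17 of the 85 list calls remained, and median ratio scaling ended 17 of the 85 and turned 1 more, which did not pass either. With an absolute log2 change of at least 1 the counts were 1401, 1543 and 1500 (labelled WT days 1 to 3), 1378, 1641 and 1629 (labelled KO), 58, 58, 49 and 47 (between genotypes, days 0 to 3) and 28 (genotype by time). Without the filter, with more genes tested, they were 10171 (labelled WT day 3), 10690 (labelled KO day 3) and 201 (genotype by time). Median ratio scaling left 624, 291, 71 and 214 genes between genotypes and quantile normalization 397, 217, 70 and 214. Array weights gave 1795, 5145, 5248 and 5081, and 847 for genotype by time. A pseudocount of 0.1 gave 71 for genotype by time. With only the libraries compared, which leaves fewer samples, 45 genes were called between genotypes at day 0 and 4 at day 3; this fit does not exist for genotype by time, which uses all groups.

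Signs turned in 5 results. Under quantile normalization Krt8 in labelled WT at day 3 became 1.18, Reg2 in labelled KO at day 1 became 1.22 and Pdx1 in labelled WT at day 3 became −0.18. Pdx1 between genotypes at day 2 became 0.0132 with array weights, and with 1 library left out it ranged from −0.0326 (without labelled WT day 2 replicate 1) to 0.0258 (without labelled WT day 2 replicate 2), with 0.0181 without labelled KO day 2 replicate 0. The histone list between genotypes at day 2 turned after median ratio scaling (adjusted p = 0.705). Except where more genes or the stricter threshold account for it, the cause was not tested.

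Leaving out 1 library gave 6105 to 6389, 6396 to 6651 and 6324 to 6555 genes in labelled WT, 6188 to 6432, 6524 to 6716 and 6371 to 6599 in labelled KO, and 2170 to 2889 between genotypes at day 0. At day 1 the range was 1351 (without labelled KO replicate 1) to 2039. At day 2 it was 533 (without labelled WT replicate 2) to 1825. At day 3 it was 297 (without labelled WT replicate 2) to 1559. For genotype by time it was 61 (without labelled WT day 0 replicate 2) to 211 (without labelled WT day 0 replicate 0).

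Replicate numbers as a block gave 2298 genes between genotypes at day 3 and 271 for genotype by time, and 6935 for the paired day 1 comparison in labelled KO. Of 28 pairs of groups 7 had all 3 same-numbered correlations over 0.1, 1 of them among the 16 between genotypes. The numbers were therefore not read as pairing the genotypes. The block was still 1 factor over both genotypes. Since the libraries numbered 2 were those of female type, it also carried sex. The block ended the Reg list call in labelled KO at day 3 (adjusted p = 0.0501) and the Shisa4 call at day 0 (0.0543). With it the Pdx1 results of labelled WT at day 1 (0.0214) and between genotypes at day 3 (0.0414) passed, as did 3 lists between genotypes: ductal (0.0340) and cholesterol synthesis (0.0474) at day 2 and Reg (0.0495) at day 3. It changed no other call among the genes named and the lists tested. The random block within a genotype gave 334 for genotype by time. Depth is unknown, so its limit on low values could not be set.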

Other observations

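The test of replicate numbers was chosen after the result was seen, as were the genes named in this part.

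Some genes peaked or dipped before day 3, which comparisons with day 0 alone do not show. The β-defensin gene Defb1 stood at 3.5 ± 0.816, 73.95 ± 23.4, 17.2 ± 2.13 and 22.7 ± 6.85 FPKM at days 0, 1, 2 and 3 in labelled WT and at 4.17 ± 1.25, 32.9 ± 7.69, 8.8 ± 0.98 and 15.6 ± 3.49 in labelled KO (mean ± SD, n = 3). The tight junction gene Cldn4 also stood highest at day 1, with 409.5 ± 24.6 in labelled WT and 536 ± 87.6 in labelled KO, and at 125 ± 4.23 and 131 ± 27.6 at day 3. Bhlha15, a transcription factor of mature acini, was lowest at day 2 in both genotypes (0.811 ± 0.149 and 1.02 ± 0.251) and stood at 3.33 ± 0.661 and 4.16 ± 1.09 at day 3. The gap junction gene Gjb1 had the same shape, with 1.91 ± 0.417 and 2.24 ± 0.431 at day 2 and 4.99 ± 0.52 and 7.89 ± 2.32 at day 3. Nr5a2, an acinar nuclear receptor, went from 3.31 ± 0.191 and 3.22 ± 0.127 at day 1 to 5.97 ± 0.716 and 5.69 ± 0.655 at day 3. Differences among days 1, 2 and 3 were not tested.

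Ptf1a, whose promoter drives the Cre, kept between 3.28 and 4.93 FPKM in every group mean while its partner gene Rbpjl dropped. Ptf1a stood at 3.3 ± 0.572, 4.24 ± 1.21, 3.98 ± 0.457 and 4.93 ± 0.769 FPKM in labelled WT and at 4.22 ± 1.44, 3.96 ± 0.676, 3.28 ± 0.393 and 3.35 ± 0.636 in labelled KO. Rbpjl stood at 41.9 ± 2.72, 5.36 ± 0.305, 3.86 ± 0.885 and 4.46 ± 0.934 in labelled WT and at 42.2 ± 1.18, 3.11 ± 0.459, 2.45 ± 0.566 and 2.86 ± 0.85 in labelled KO.

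Replicate numbers separated the sexes. The X-inactivation transcript Xist lay between 7.72 and 15.5 FPKM in the 8 libraries numbered 2 and between 0.0133 and 0.114 in the other 16. The Y-linked helicase gene Ddx3y lay between 0.00327 and 0.069 in the libraries numbered 2 and between 1.79 and 5.58 in the others. Each group therefore held 1 library of female and 2 of male type.

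The hypothesis that a number marks 1 animal across the 4 days of a genotype was tested by correlating the deviations of 8682 autosomal genes from their group means between days. The numbering in the labels gave a mean r of 0.14 in labelled WT and 0.15 in labelled KO, across genes, which are not independent replicates, against at most 0.12 in any other numbering for each genotype. It was 1 of 216 numberings in labelled WT and 1 of 216 in labelled KO to reach its value (exact permutation p = 0.0046 each). Since the sexes could carry this, numberings that exchange only 0 and 1, both of male type, were also compared, and the labels' numbering was highest among 8 in each genotype. With 8 numberings no share can lie under 0.05, so this does not exclude sex as the source. Libraries of 1 number that were prepared or sequenced together would also correlate, so the test cannot tell an animal from a batch. Rufy4 is 1 of the genes that followed a number. Labelled WT replicate 2 held 23.1, 24.0, 18.9 and 7.26 FPKM at days 0 to 3, against 1.25 to 6.70 in the other labelled WT libraries. Likewise 1 labelled WT replicate was highest at each day for Apobec3 (replicate 1) and Ckb (replicate 0), and lowest for C4b (replicate 1). The labels do not state this. If it is so, libraries of different days are not independent samples of animals, and genotype differences that recur at all 4 days may rest on 3 animals per genotype and not on 12.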
